A study of Mus musculus with 10 samples.

How the data were processed

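Adult olfactory epithelium of C57BL6 mice was collected 9 days after a methimazole lesion, dissociated with enzymes, grown as adherent cultures on gelatin in a neural proliferation medium with EGF and FGF2, and transduced with lentivirus, per the labels' protocols. Stranded total RNA libraries were made from 500 ng of RNA. Reads were demultiplexed with bcl2fastq 2.17, trimmed with Trim Galore 0.4.3 and aligned with STAR 2.5.0a to mm10, per the submitters' processing notes. The annotation release is not given in the sources used here. The deposited values are raw, unnormalized read counts per Ensembl gene for each library, in STAR's layout, with an unstranded, a forward-strand and a reverse-strand count. Per the labels, 4 libraries carried the non-targeting hairpin, 3 the Cbx7 hairpin and 3 the Cbx8 hairpin, while the series design text gives 3 replicates per treatment.

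The reverse-strand count was used, since the forward-strand count held only 3.42 to 10.4% of the stranded gene counts. Its totals, the depth of each library, ran from 22763014 to 50463172. The 4 totals that name no gene were left out of library sizes and tests: unmapped reads (5.03 to 21.7% of all reads), reads that map to several places (15.4 to 22.1%), reads in no gene (12.5 to 23.6%) and ambiguous reads (0.290 to 0.637%). Of 41091 gene identifiers, 40217 matched the GENCODE M21 annotation of GRCm38, which gave symbols and coordinates, and the 874 others held at most 0.272% of the counts of a library. Reads shared by near-identical genes, such as Gm10800 and other repeat-derived models, are counted uncertainly. Counts of libraries of the same group differed by more than sampling noise in each of 12 pairs (chi-square per degree of freedom 28.1 to 445). No library thus merely repeated another, and each counted as 1 replicate, but this does not show separate cultures or animals. The lowest value, 28.1, was that of shCBX8 1 and 6 (r = 0.990 of log2 CPM), and the next lowest was 111.

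Genes with low counts were removed with edgeR's filterByExpr (minimum count of 10), which left 16669 genes. Libraries were scaled by trimmed mean of M values, and edgeR's quasi-likelihood test was fitted over all 10 libraries with the group as the only factor (common biological coefficient of variation 0.375). Both knockdowns were compared with control and with each other. P-values were adjusted by the Benjamini-Hochberg method over all genes, with 0.05 as the threshold. Levels are CPM as edgeR computes them, that is, counts relative to the scaled library size. Targeted genes were also compared by an exact two-sided permutation test on log2(CPM + 1). Because the 3 groups share 1 estimate of the spread, leaving out a library of any group can move each comparison. The median 95% interval of a log2 fold change reached 0.60 to each side for shCBX7 and 0.61 for shCBX8 against control, and 0.65 between the knockdowns.

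Gene lists were tested with limma's camera (preset correlation of 0.01, at least 5 tested members, adjusted over the 31 lists of a comparison), with an estimated correlation and with fry. The lists were PRC1 subunits, PRC2 subunits, Hox genes, developmental transcription factors, cyclin-dependent kinase inhibitors, senescence-associated secreted factors, S phase, mitosis, p53 targets, interferon-stimulated genes, the integrated stress and unfolded protein responses, cholesterol biosynthesis, Notch pathway, Wnt targets, TGF-beta and BMP targets, ERK targets, immediate early genes, and extracellular matrix and proteases. Marker lists covered horizontal basal cells, globose basal cells and neuronal progenitors, immature and mature olfactory neurons, sustentacular cells, microvillar cells, Bowman glands, respiratory cells, ensheathing and Schwann cells, fibroblasts, smooth muscle and pericytes, endothelium, and immune cells. In all 33 lists were written, and the mitochondrially encoded and sex-linked genes were not tested. Other pathway sets were also looked at and are not reported here.

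The groups, tests, gene lists, naming rule and the settings listed here were fixed before the data were examined. Genes are named by this rule: CBX genes of PRC1 and Cdkn2a; the 8 largest rises and 8 largest falls against control (5 and 5 between the knockdowns) among protein-coding genes that passed, had a mean of at least 5 CPM and did not overlap between the groups, or the 3 smallest p in each direction where none passed; and up to 4 members of each list with the smallest p. Some items that the rule takes are not reported here. Each result was also computed with median-ratio (RLE) scaling, library size only, no filter, a mean of at least 1 CPM, DESeq2's Wald test, unstranded counts, only the 2 groups compared, the replicate number as a block, each library left out, the 10 most abundant genes left out, and a threshold of 0.01. The controls were also split 2 and 2. Subtraction of forward-strand counts, a background covariate, omission of shCTR 1 and 2, and lists of lysosomal and striated muscle contractile genes were added after the data had been seen.

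The fit was tested on simulated counts for 16669 genes with known changes. In the simulated shCBX7 comparison, 0% of 67 genes changed 1.5-fold were recovered, 11.9% of 67 changed 2-fold and 59.1% of 66 changed 4-fold, with 0 false calls among 49. For shCBX8 these shares were 0%, 11.9% and 77.3%, with 3 false calls among 67 (4.48%). Most simulated 2-fold changes were thus missed. A list of shifted genes was called in both, with 1 and 0 of 30 unshifted lists. This does not check lists of correlated genes. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.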

Results

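The series addressed what loss of CBX paralogs does in the regenerating olfactory epithelium. CBX7 and CBX8 are chromodomain subunits of Polycomb repressive complex 1 (PRC1), which binds methylated histone H3 and keeps developmental genes repressed. Total RNA was sequenced from adherent cultures of mouse olfactory epithelium dissociated 9 days after a methimazole lesion, a drug treatment that destroys the epithelium and starts its regrowth from basal stem cells. The cultures had been transduced with lentiviral short hairpin RNAs (shRNAs). There were 4 libraries with a non-targeting hairpin (shCTR replicates 1, 2, 5 and 6), 3 with a hairpin against Cbx7 (shCBX7 replicates 1, 2 and 5) and 3 with a hairpin against Cbx8 (shCBX8 replicates 1, 2 and 6). The labels call these biologic replicates without saying whether they came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. Gene counts were 26549274, 22763014, 27661015 and 35414943 in the shCTR libraries, 50463172, 35144409 and 40596975 in the shCBX7 libraries, and 43731320, 31665704 and 41670399 in the shCBX8 libraries.

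Cbx8 transcripts fell in the shCBX8 libraries, whereas Cbx7 transcripts did not change beyond the replicate spread in the shCBX7 libraries. Cbx8 (ENSMUSG00000025578, chromosome 11, 119036305 to 119040969, minus strand, GRCm38/mm10) measured 12.4, 15.9, 10.2, 10.8 CPM in shCTR 1, 2, 5 and 6 and 4.99, 5.14, 4.71 CPM in shCBX8 1, 2 and 6. Its log2 fold change in shCBX8 was -1.31 (SE 0.22, adjusted p = 0.00416), and an exact two-sided permutation test on log2(CPM + 1) gave p = 0.0286, the smallest that 35 splits of 7 libraries allow. With the background covariate described further on, chosen after seeing the data, its value was -1.05 with adjusted p = 0.0831. Cbx7 (ENSMUSG00000053411, chromosome 15, 79915807 to 79971119, minus strand) measured 17.7, 16.4, 13.5, 5.30 CPM in shCTR 1, 2, 5 and 6 and 3.64, 8.02, 13.1 CPM in shCBX7 1, 2 and 5. Its log2 fold change in shCBX7 was -0.67 (SE 0.48, adjusted p = 0.929), with an exact permutation p = 0.314, and it was -1.17 without shCBX7 5 (adjusted p = 0.476), -0.29 without shCBX7 1, -0.19 without shCTR 1 and 2 (both adjusted p over 0.99) and 1.78 with the background covariate (adjusted p = 0.633). The level of Cbx7 therefore does not check the shCBX7 label, and shCBX7 below names the libraries by that label. Cbx8 in shCBX7 had a log2 fold change of 0.01 (exact permutation p = 1), and Cbx7 in shCBX8 one of -0.17 (exact permutation p = 0.914).

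Among the other CBX genes of PRC1, Cbx6 fell in shCBX8, from 189 ± 63.3 CPM (SD, n = 4) to 81.7 ± 12.8 CPM (n = 3), a log2 fold change of -1.21 (SE 0.27, adjusted p = 0.0112). Cbx2 had a log2 fold change of -0.48 (SE 0.18, adjusted p = 0.0651) in shCBX8 and did not pass. In shCBX7 the values were 0.26 for Cbx2 and -0.12 for Cbx6, neither passing. Cdkn2a (chromosome 4, 89274471 to 89294653), which encodes the cell cycle inhibitors p16Ink4a and p19Arf and is a classical Polycomb target, fell in shCBX8 from 124 ± 22.8 CPM to 64.7 ± 13.8 CPM, a log2 fold change of -0.94 (SE 0.21, adjusted p = 0.0109). Its value in shCBX7 was 0.15 (SE 0.20, adjusted p = 0.952). The control mean of Cbx6 includes 283 CPM in shCTR 2, far above the others. The call of Cbx6 ended without shCBX8 1 or 6 (adjusted p = 0.0525 to 0.0538) and with the background covariate (-1.0, SE 0.48, adjusted p = 0.185), and that of Cdkn2a without shCBX8 1 or 6 (adjusted p = 0.0557 to 0.0561).

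**Figure D1:**
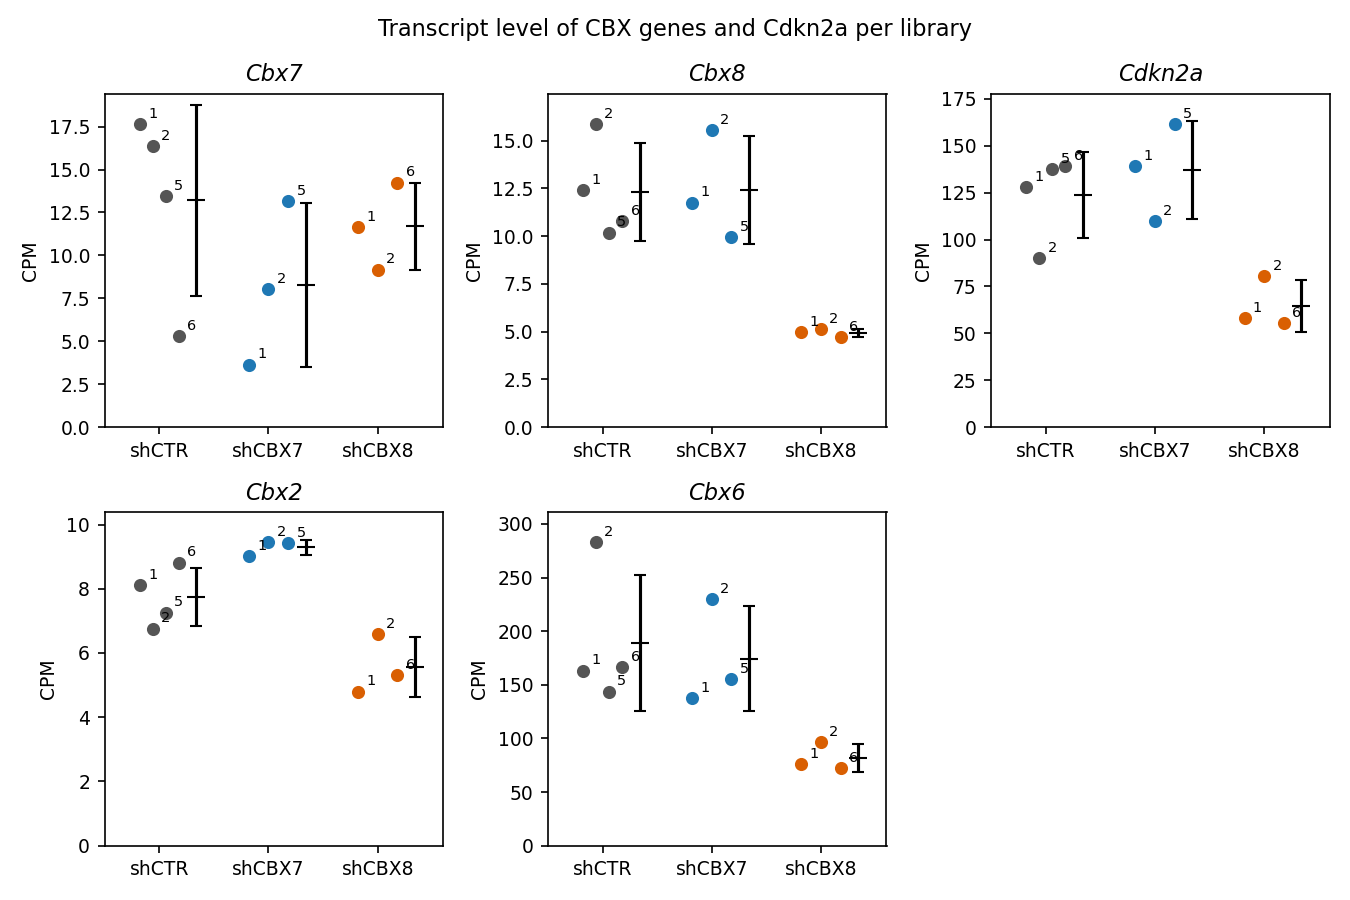
Transcript level in CPM (counts relative to the scaled library size) of Cbx7, Cbx8, Cdkn2a, Cbx2 and Cbx6 in each library, with the replicate number beside each point and the group mean with SD as the bar (n = 4, 3 and 3). Cbx8 lies between 4.71 and 5.14 CPM in shCBX8, under each of the other 7 libraries, and Cbx7 overlaps between the groups.

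The libraries differed in 2 measures that move with the groups. The first was background. Unmapped reads made up 21.7, 19.6, 14.0 and 9.83% of the reads in shCTR 1, 2, 5 and 6, against 5.03 to 7.81% in the 6 knockdown libraries. Gm10800, a gene model of satellite-like repeat sequence and the most abundant entry, took 10.4, 8.34, 4.14 and 1.96% of gene counts in shCTR 1, 2, 5 and 6 and 0.737 to 1.51% in the knockdown libraries. Counts on the strand opposite to transcription over 1653 olfactory and vomeronasal receptor genes, which are rarely expressed outside their own neurons, were 111, 89.5, 68.8 and 32.9 CPM in shCTR 1, 2, 5 and 6 and 11 to 27.4 CPM in the knockdown libraries. The log2 of this last value is the background covariate. The second measure was the fibroblast marker list, whose mean log2 CPM over 22 members was 8.36, 9.69, 7.74 and 7.55 in shCTR 1, 2, 5 and 6, 7.52, 8.89 and 7.60 in shCBX7 1, 2 and 5, and 4.82, 7.04 and 4.19 in shCBX8 1, 2 and 6.

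**Figure D2:**
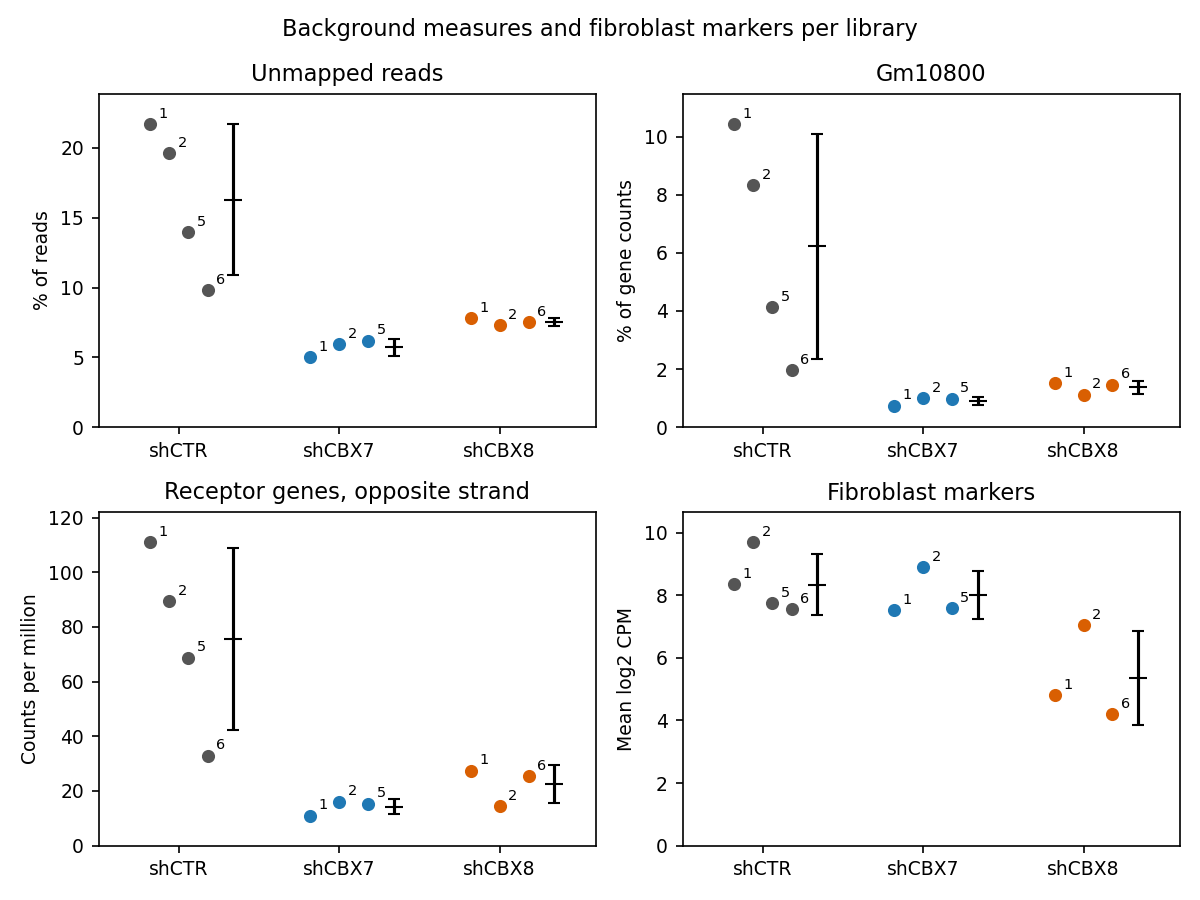
Background measures and fibroblast markers in each library, with the replicate number beside each point and the group mean with SD as the bar (n = 4, 3 and 3): unmapped reads in percent, Gm10800 in percent of gene counts, receptor gene counts on the opposite strand in CPM, and the mean log2 CPM of 22 fibroblast markers. The shCTR libraries 1 and 2 lie highest in the first 3 panels, and the shCBX8 libraries 1 and 6 lie lowest for the fibroblast markers.

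The first principal component of log2 CPM held 55.9% of the variance and set the shCBX8 libraries, at 132, 53.6 and 139.7 for replicates 1, 2 and 6, apart from the other 7 libraries, at -97.4 to -15.7. The shCTR and shCBX7 libraries were mixed on it, and shCBX8 2 lay nearest to them of the shCBX8 libraries.

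**Figure D3:**
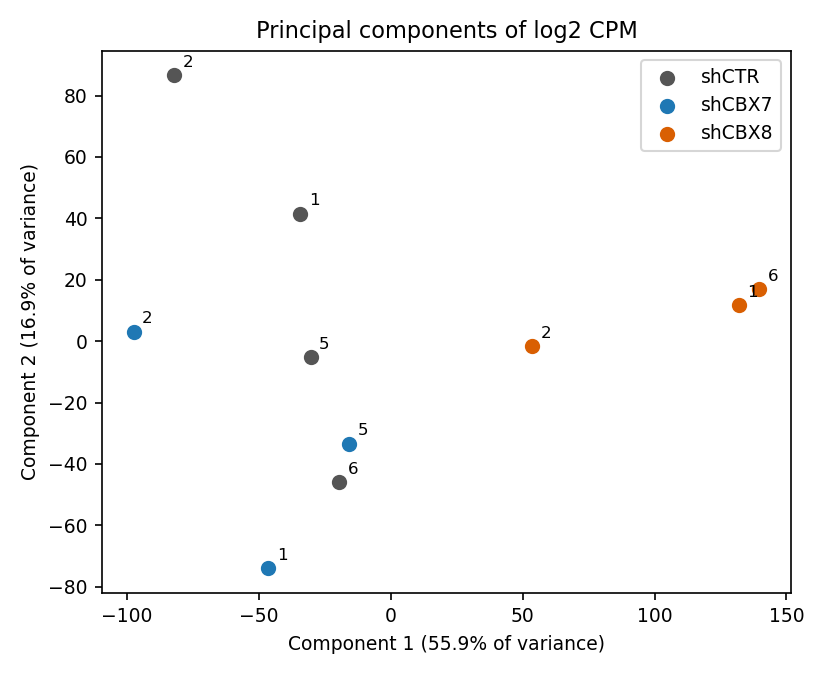
First and second principal components of log2 CPM (55.9% and 16.9% of the variance) for the 10 libraries, with the replicate number beside each point. The shCBX8 libraries lie at 53.6 or more on the first component and the shCTR and shCBX7 libraries at -15.7 or less.

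The first comparison asked which genes differ between cultures with the Cbx7 hairpin (n = 3) and the control hairpin (n = 4). No gene passed. Here and for the genes that follow, the value before a standard error (SE) is the log2 fold change. The genes with the smallest p among those with higher values were Dctn3, a dynactin subunit, at 0.37 (SE 0.09, adjusted p = 0.317), Prdx6, an antioxidant peroxiredoxin, at 0.67 (SE 0.17, adjusted p = 0.351), and Uchl1, a ubiquitin hydrolase of neurons, at 1.12 (SE 0.30, adjusted p = 0.370). Among genes with lower values they were Scube1 at -2.37 (SE 0.58, adjusted p = 0.317), the cytokine receptor gene Lifr at -1.02 (SE 0.27, adjusted p = 0.356) and the transcription factor gene Runx1 at -0.80 (SE 0.21, adjusted p = 0.365). None of these 6 passed, and Scube1 was far higher in shCTR 2 (58.9 CPM) than in the other shCTR libraries. The edgeR quasi-likelihood test called 0 of 16669 genes, with 975 at an unadjusted p under 0.05 where chance gives 833, 169 of them higher and 806 lower. DESeq2 called 91, of which 89 were lower, and edgeR called 41 without shCTR 6, of which 40 were lower. The median 95% interval of a log2 fold change reached 0.60 to each side, or 0.42 for genes with a mean of at least 5 CPM. In the simulation, where few genes changed, 11.9% of 2-fold and 59.1% of 4-fold changes were recovered. Most 2-fold changes could thus be missed if few genes changed here.

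Of the 31 gene lists tested, 5 passed camera in shCBX7, although none of their members passed over all genes. Medians of lists are of the log2 fold change of their members. Cell cycle genes had higher values, both the 35 S phase genes (median 0.29, camera adjusted p = 8.37e-07) and the 36 mitosis genes (median 0.27, camera adjusted p = 6.90e-05). Members with the smallest p were Rfc2, a clamp loader subunit, at 0.33 (SE 0.09, adjusted p = 0.436) and the spindle checkpoint gene Bub3 at 0.25 (SE 0.13, adjusted p = 0.915). The 23 genes of cholesterol biosynthesis also had higher values (median 0.22, camera adjusted p = 0.0118). Lower values were found for the 8 Hox genes (median -1.06, camera adjusted p = 0.0244) and the 65 other developmental transcription factors (median -0.24, camera adjusted p = 0.0118). Adjusted over the list alone, 3 of the latter fell, Lhx4, Pax8 and Wt1, and no member of another list passed. Their mean levels over the 10 libraries were under 1 CPM, as for Lhx4, a LIM homeobox gene, at -3.18 (SE 0.62, adjusted p = 0.247) with 0.707 ± 0.376 CPM in shCTR and 0.0765 ± 0.0375 CPM in shCBX7. The number of lists that passed ran from 3 without shCTR 1 to 12 without shCBX7 5, was 9 without shCTR 2 or 5 and 8 without shCBX7 2, and was 0 with an estimated correlation (adjusted p = 0.946 for each of the 5).

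The background measures moved with these lists. With the background covariate the calls of S phase (median -0.12, adjusted p = 0.721), mitosis (median 0.21, adjusted p = 0.467) and Hox genes (median 1.41, adjusted p = 0.291) ended, with the median turned for S phase and Hox genes. Cholesterol biosynthesis turned and passed in this extrapolated fit (median -1.01, adjusted p = 6.49e-15). After forward-strand counts were subtracted, the calls of Hox genes (median 0.18, adjusted p = 0.770, turned) and developmental transcription factors (median -0.18, adjusted p = 0.493) ended, and the other 3 passed. Without shCTR 1 and 2 the calls of Hox genes (median -0.87, adjusted p = 0.707) and cholesterol biosynthesis (median -0.11, adjusted p = 0.686, turned) ended. With the replicate number as a block the mitosis call ended (median 0.13, adjusted p = 0.0517). When 1 library was left out, the mitosis call ended without shCTR 2 (adjusted p = 0.252), that of Hox genes without shCTR 1 or 2 (adjusted p = 0.0591 to 0.116), that of developmental transcription factors without shCTR 6 or shCBX7 1 (adjusted p = 0.116 to 0.119) and that of cholesterol biosynthesis without shCTR 1 or shCBX7 1 (adjusted p = 0.164 to 0.351). Other lists passed when a library was left out. Without shCTR 2 or shCBX7 5 these were horizontal basal cell, sustentacular, Bowman gland and immune cell markers (adjusted p = 3.90e-07 to 0.0231). Respiratory markers passed without shCTR 2 or 5, shCBX7 1 or 5 or shCBX8 1, 2 or 6 (adjusted p = 0.00274 to 0.0315). Ensheathing and Schwann cell markers did so without shCTR 2, shCBX7 1 or 5 or shCBX8 2 (adjusted p = 0.00201 to 0.0357). The same held for smooth muscle markers without shCTR 5 (adjusted p = 0.0311) and endothelial markers without shCBX7 1 (adjusted p = 0.0120). It held as well for p53 targets without shCTR 5 or shCBX7 2 (adjusted p = 0.0289 to 0.0308), ERK targets without shCTR 5 or 6 or shCBX7 2 (adjusted p = 6.12e-06 to 0.0188) and immediate early genes without shCBX7 2 or 5 (adjusted p = 0.0142 to 0.0284).

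Other settings also brought uncalled lists past camera in shCBX7, all with lower values except p53 targets, stress genes, TGF-beta and BMP targets and, without the covariate, ERK targets. With the covariate these were horizontal basal cell markers, immature neuron markers and ERK targets (adjusted p = 1.53e-07 to 0.0428). After forward-strand counts were subtracted these were ensheathing and Schwann cell markers (adjusted p = 0.0114). Without shCTR 1 and 2 these were horizontal basal cell markers, sustentacular markers, Bowman gland markers, respiratory markers, ensheathing and Schwann cell markers and Notch pathway genes (adjusted p = 5.42e-05 to 0.0169). Without a low-count filter these were p53 targets, stress genes, TGF-beta and BMP targets and ERK targets (adjusted p = 0.000747 to 0.0494). With a mean of at least 1 CPM these were respiratory markers, ensheathing and Schwann cell markers and smooth muscle markers (adjusted p = 0.000836 to 0.0388). With the replicate number as a block these were ensheathing and Schwann cell markers, fibroblast markers and ERK targets (adjusted p = 0.0117 to 0.0339). With only the 2 groups compared these were respiratory markers and ensheathing and Schwann cell markers (adjusted p = 0.0188 to 0.0269). In all 31 lists 0 members passed over all genes in shCBX7. Medians of the 26 lists that were not called lay between -0.64 for respiratory markers and 0.33 for ERK targets. The median, the mean and the camera direction differed in sign for 8 uncalled lists, namely PRC1 subunits, PRC2 subunits, cyclin-dependent kinase inhibitors, senescence-associated factors, progenitor markers, immature neuron markers, interferon-stimulated genes and immediate early genes.

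The second comparison asked which genes differ between cultures with the Cbx8 hairpin (n = 3) and the control hairpin (n = 4), and 5478 of 16669 genes changed. Acta1, skeletal alpha-actin (ENSMUSG00000031972, chromosome 8, 123891769 to 123894751), rose from 0.425 ± 0.105 CPM (SD, n = 4) to 37.7 ± 21.7 CPM (n = 3), a log2 fold change of 6.47 (SE 0.95, adjusted p = 0.00267), and Mybpc2, a fast-muscle myosin-binding protein, by 5.51 (SE 1.16, adjusted p = 0.00917). Lrp2, the endocytic receptor megalin (chromosome 2, 69424340 to 69586065), rose by 5.48 (SE 0.75, adjusted p = 0.00226) and Chrnb2, a nicotinic receptor subunit (chromosome 3, 89746195 to 89764632), by 4.49 (SE 0.27, adjusted p = 0.000372). Edn2, which encodes endothelin 2, rose by 6.13 (SE 1.36, adjusted p = 0.0108), the carboxypeptidase gene Cpa4 by 4.74 (SE 0.85, adjusted p = 0.00510), the chemokine gene Ccl20 by 4.59 (SE 1.13, adjusted p = 0.0159) and Bex1 by 4.55 (SE 0.87, adjusted p = 0.00638).

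Among the largest falls, Igf2, a growth factor gene (ENSMUSG00000048583, chromosome 7, 142650766 to 142666816), went from 276 ± 136 CPM to 2.87 ± 2.57 CPM, a log2 fold change of -6.60 (SE 0.78, adjusted p = 0.00156). Inmt, which encodes an indole methyltransferase, changed at -8.68 (SE 1.74, adjusted p = 0.00746), the angiotensinogen gene Agt at -7.21 (SE 1.12, adjusted p = 0.00339) and Lrrc17 at -6.58 (SE 1.25, adjusted p = 0.00627). Matrix genes in this group were Fmod, fibromodulin, which went from 13.6 ± 23.3 CPM to 0.0142 ± 0.0123 CPM (-9.48, adjusted p = 0.0108), Aspn, asporin, at -7.34 (SE 1.76, adjusted p = 0.0143), and Eln, elastin, at -6.26 (SE 2.06, adjusted p = 0.0432). The lipoprotein lipase gene Lpl changed at -6.08 (SE 1.86, adjusted p = 0.0344). In shCTR 2 Fmod measured 48.5 CPM, Eln 31.6 CPM and Lpl 158 CPM, far above the other shCTR libraries. When 1 library was left out, calls ended for Ccl20 without shCBX8 1 (adjusted p = 0.0592), Fmod without shCBX8 1 (adjusted p = 0.0506), Aspn without shCBX8 1 or 6 (adjusted p = 0.0555 to 0.0625), Eln without shCTR 1 or 2 or shCBX8 1, 2 or 6 (adjusted p = 0.0589 to 0.136) and Lpl without shCBX8 1, 2 or 6 (adjusted p = 0.0762 to 0.115). Without shCTR 2, Eln was at -3.93 and Lpl at -2.69. The call of Lpl also ended with the replicate number as a block (-3.86, adjusted p = 0.0619). The calls of Edn2, Cpa4, Ccl20, Bex1, Fmod, Inmt, Aspn, Agt, Lrrc17, Eln and Lpl ended with the covariate (adjusted p = 0.0610 to 0.868). The log2 fold change with the covariate was 7.37 (SE 2.5) for Edn2, 4.21 (SE 1.52) for Cpa4, 5.77 (SE 1.92) for Ccl20, 4.16 (SE 1.46) for Bex1, -3.38 (SE 2.20) for Fmod, -6.90 (SE 2.08) for Inmt, -4.84 (SE 3.51) for Aspn, -4.82 (SE 1.65) for Agt, -1.89 (SE 1.02) for Lrrc17, -1.88 (SE 2.54) for Eln and -0.71 (SE 2.5) for Lpl. Omission of shCTR 1 and 2 ended the calls of Edn2, Ccl20, Aspn, Eln and Lpl (adjusted p = 0.0513 to 0.227), with Eln at -2.97, Lpl at -2.52 and Fmod at -6.16.

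Of the 5478 changed genes 2827 were higher and 2651 lower (51.6% higher), 3055 by more than 2-fold and 1401 by more than 4-fold. In 5172 of them the shCBX8 and shCTR libraries did not overlap. Scaling by library size alone gave 5604 genes, 67.2% of them higher, and the median log2 fold change of all genes was then 0.17, against -0.01 with TMM scaling. The count was 2261 without shCBX8 1, 2279 without shCBX8 6, 2311 with the covariate and 2409 without shCTR 1 and 2. Of 112 called genes that the naming rule takes, 49 lost their call without shCBX8 1, 49 without shCBX8 6 and 73 with the covariate, and 27 kept it in every setting that tested them at the threshold of 0.05. A call that ends with the covariate need not mean a change that is gone. The 73 genes kept a median of 85.6% of their log2 fold change (quartiles 62.9 to 104%), and their median SE went from 0.55 to 0.97.

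Of 31 gene lists, 10 passed camera, 4 upward and 6 downward. Without shCBX8 6 the number was 4, and none passed with an estimated correlation (lowest adjusted p = 0.642). Counts adjusted over the list alone are given where they differ. Polycomb genes moved in both directions. Of 18 tested PRC1 subunits, 2 rose and 5 fell (median -0.27, adjusted p = 0.276 by camera and 0.00485 by fry). Phc1, a polyhomeotic subunit, fell, at -1.29 (SE 0.16, adjusted p = 0.00156), and Pcgf6 and Yaf2, subunits of variant complexes, rose by 0.95 (SE 0.17, adjusted p = 0.00519) and 0.70 (SE 0.15, adjusted p = 0.00959). Of 11 tested PRC2 subunits, 2 rose and 1 fell (median 0.15, camera adjusted p = 0.549). Suz12, a core subunit of the H3 methyltransferase complex, rose by 1.08 (SE 0.17, adjusted p = 0.00315) and Mtf2, an accessory subunit, by 0.52 (SE 0.12, adjusted p = 0.0116). Of 8 tested Hox genes, 4 rose and 0 fell (median 1.84, camera adjusted p = 0.0168, adjusted p = 0.652 with an estimated correlation). The 4 that rose, Hoxc6 (2.5), Hoxb9 (2.03), Hoxb4 (2.93) and Hoxc4 (2.79), had mean levels under 1 CPM in each group. Hoxb4 measured 0.135 ± 0.157 CPM in shCTR and 0.947 ± 0.160 CPM in shCBX8. Of 65 tested other developmental transcription factors, 6 rose and 24 fell, 8 and 26 adjusted over the list alone (median -1.39, camera adjusted p = 0.00131, adjusted p = 0.652 with an estimated correlation). Those with the smallest p fell, Foxc1, a forkhead gene of mesenchyme, at -1.77 (SE 0.19, adjusted p = 0.00124), the Iroquois genes Irx1 at -3.68 (SE 0.42, adjusted p = 0.00153) and Irx2 at -1.90 (SE 0.26, adjusted p = 0.00231), and the mesenchyme homeobox gene Meox2 at -5.25 (SE 0.74, adjusted p = 0.00249).

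For these lists, leaving out 1 library moved counts as follows. PRC1 subunits that fell numbered 1 without shCBX8 1 or 6. Hox genes that rose numbered 0 without shCBX8 1 or 6 and 1 without shCTR 5. Developmental transcription factors that rose numbered 1 without shCBX8 6, 2 without shCBX8 1 and 3 without shCTR 1 or 5, and those that fell numbered 12 without shCBX8 1 or 6. The Hox call ended without shCBX7 1, 2 or 5 or shCBX8 1, 2 or 6 (adjusted p = 0.206 to 0.384), without a low-count filter (median -0.29, adjusted p = 0.588) and with unstranded counts (median 0.32, adjusted p = 0.899). All of these settings tested 13 or more Hox genes, and it held only where 8 or 9 were tested. The calls of Hoxc6, Hoxb9, Hoxb4 and Hoxc4 all ended with the replicate number as a block (adjusted p = 0.05004 to 0.0569), where their log2 fold changes were 2.26, 2.09, 2.97 and 3.03. They also ended without shCBX8 1 or 6 (adjusted p = 0.0541 to 0.0963). Those of Hoxc6, Hoxb9 and Hoxc4 ended with unstranded counts (1.17, 1.27 and 1.09, adjusted p = 0.146 to 0.339), whereas after forward-strand counts were subtracted they were at 6.78, 4.0 and 7.34. Those of Hoxb9, Hoxb4 and Hoxc4 ended without shCTR 5 (adjusted p = 0.0531 to 0.0829), that of Hoxb9 without shCTR 6 (adjusted p = 0.0510) and that of Hoxc4 without shCBX8 2 (adjusted p = 0.0725). The call of Mtf2 ended without shCBX8 1 (adjusted p = 0.0562). The calls of Pcgf6, Yaf2, Mtf2, Hoxc6 and Hoxc4 ended with the covariate (adjusted p = 0.0745 to 0.147). Log2 fold changes in that fit were 0.92 (SE 0.30) for Pcgf6, 0.61 (SE 0.26) for Yaf2, 0.57 (SE 0.21) for Mtf2, 3.19 (SE 1.19) for Hoxc6 and 4.15 (SE 1.74) for Hoxc4, and 5.77 for Hoxb4 and 3.54 for Hoxb9, which passed. The fit without shCTR 1 and 2 ended the calls of Yaf2 and Mtf2 (adjusted p = 0.0649 to 0.0655) and put Hoxb4 at 8.21 and Hoxc4 at 5.01.

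Genes of fibroblasts and of extracellular matrix had lower values in shCBX8. Of 22 tested fibroblast markers, 0 rose and 10 fell, 0 and 13 adjusted over the list alone (median -2.5, camera adjusted p = 2.75e-05, adjusted p = 0.652 with an estimated correlation). Postn, the matrix protein periostin, fell from 2193 ± 2005 CPM to 42.1 ± 13.8 CPM, at -5.70 (SE 1.14, adjusted p = 0.00754), and the collagen VI gene Col6a3 at -2.16 (SE 0.51, adjusted p = 0.0137). Of 34 tested genes of extracellular matrix and proteases, 3 rose and 17 fell, 4 and 18 adjusted over the list alone (median -1.40, camera adjusted p = 0.000220, adjusted p = 0.652 with an estimated correlation). The paired collagen IV genes of basement membranes, Col4a1 (ENSMUSG00000031502, chromosome 8, 11198423 to 11312826) and Col4a2, fell, at -2.56 (SE 0.21, adjusted p = 0.000751) and -2.40 (SE 0.21, adjusted p = 0.000751), and the fibrillar collagen genes Col11a1 and Col5a2 at -4.79 (SE 0.77, adjusted p = 0.00366) and -3.87 (SE 0.71, adjusted p = 0.00563). Fibroblast markers that fell numbered 1 without shCBX8 1 or 6, 5 without shCTR 2, 6 without shCTR 5 and 16 without shCBX8 2. Matrix genes that rose numbered 0 without shCBX8 6 and 1 without shCTR 1 or 5 or shCBX8 1, and those that fell numbered 6 without shCBX8 1 or 6. The call of Col6a3 ended without shCBX8 1 or 6 (adjusted p = 0.0592 to 0.0610). The calls of Postn, Col11a1 and Col5a2 ended with the covariate (adjusted p = 0.108 to 0.675). With it the log2 fold change was -0.83 (SE 1.23) for Postn, -3.01 (SE 1.21) for Col11a1 and -3.47 (SE 1.30) for Col5a2. Without shCTR 1 and 2 the call of Col6a3 ended (adjusted p = 0.0566).

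**Figure D4:**
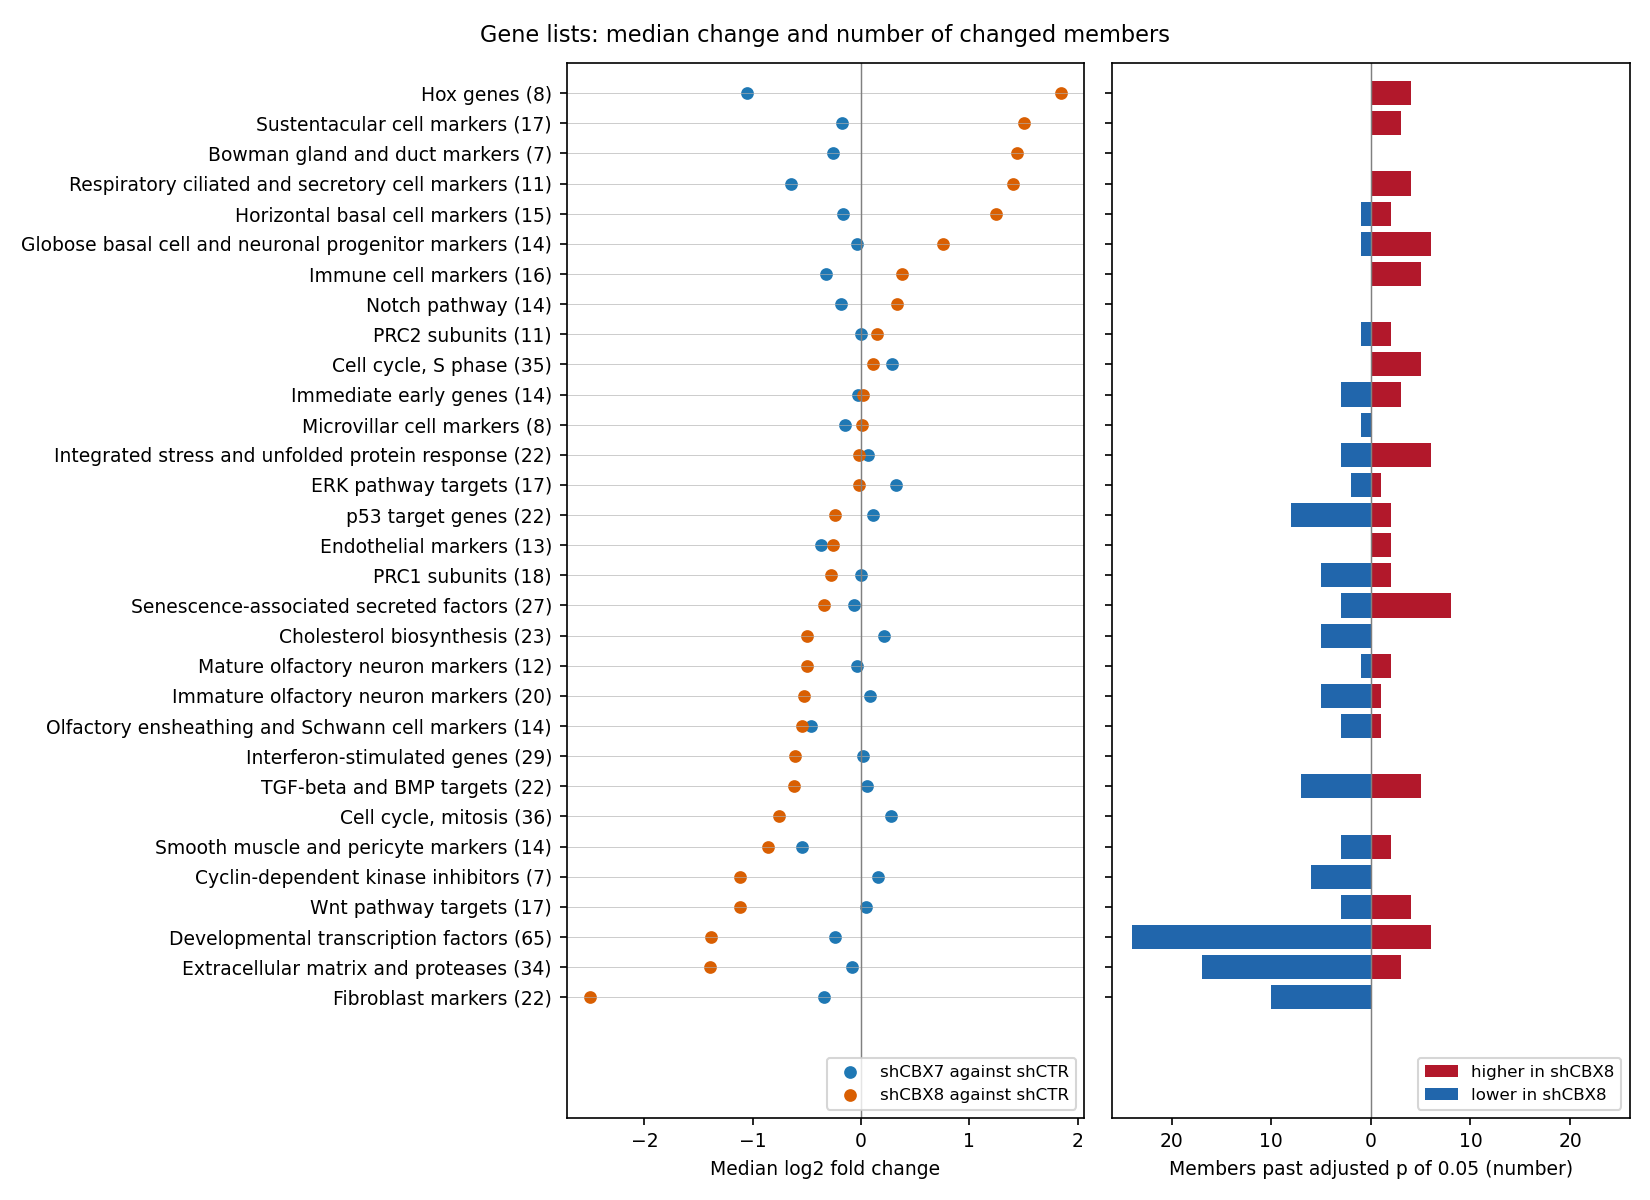
Median log2 fold change of each of the 31 gene lists against shCTR in shCBX7 and shCBX8 (left, points, with the number of tested members in parentheses) and the number of members that rose or fell in shCBX8 at an adjusted p under 0.05 over all genes (right, bars). Medians in shCBX8 run from -2.5 for fibroblast markers to 1.84 for Hox genes.

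Markers of other mesenchymal, vascular, glial and immune cells moved less uniformly. Of 14 tested smooth muscle and pericyte markers, 2 rose and 3 fell (median -0.86, camera adjusted p = 0.504). The pericyte proteoglycan gene Cspg4 fell, at -3.04 (SE 0.66, adjusted p = 0.0102) and the adhesion gene Mcam rose by 3.05 (SE 0.70, adjusted p = 0.0123). Of 13 tested endothelial markers, 2 rose and 0 fell, 0 and 0 adjusted over the list alone (median -0.26, camera adjusted p = 0.951). Vwf, von Willebrand factor, rose by 1.84 (SE 0.54, adjusted p = 0.0303). Of 14 tested olfactory ensheathing and Schwann cell markers, 1 rose and 3 fell, 2 and 3 adjusted over the list alone (median -0.54, camera adjusted p = 0.822). Mbp, myelin basic protein, rose by 1.18 (SE 0.23, adjusted p = 0.00731). Of 16 tested immune cell markers, 5 rose and 0 fell (median 0.38, camera adjusted p = 0.0869). The MHC class II genes H2-Ab1 and H2-Aa rose by 3.08 (SE 0.50, adjusted p = 0.00377) and 4.04 (SE 0.64, adjusted p = 0.00537), to 2.28 ± 1.16 CPM for H2-Aa, and the macrophage gene Cd68 by 1.69 (SE 0.34, adjusted p = 0.00725). Smooth muscle markers that fell numbered 1 without shCBX8 1 or 6. Ensheathing and Schwann cell markers that rose numbered 3 without shCBX7 2 or shCBX8 2, and those that fell numbered 0 without shCBX8 1 or 6. Immune cell markers that rose numbered 3 without shCTR 5 or shCBX8 1 or 6. The immune list passed without shCTR 1 or shCBX8 2 (adjusted p = 0.0402 to 0.0454). It also passed after forward-strand counts were subtracted (median 1.59, adjusted p = 0.0108), with the covariate (median 1.75, adjusted p = 0.0172) and without shCTR 1 and 2 (median 0.65, adjusted p = 0.0456). The call of Vwf ended without shCTR 1, 5 or 6 or shCBX8 1, 2 or 6 (adjusted p = 0.0548 to 0.0832). The calls of Mcam, Vwf, Mbp, H2-Ab1 and Cd68 ended with the covariate (adjusted p = 0.0559 to 0.198). The log2 fold change with the covariate was 2.24 (SE 1.1) for Mcam, 2.74 (SE 1.18) for Vwf, 1.45 (SE 0.42) for Mbp, 3.02 (SE 0.91) for H2-Ab1 and 1.54 (SE 0.58) for Cd68, and 6.85 for H2-Aa, which passed. Omission of shCTR 1 and 2 ended the call of Mcam (adjusted p = 0.0628) and put Vwf at 2.88.

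Olfactory lineage markers were higher in some lists and mixed in others. Of 14 tested markers of globose basal cells and neuronal progenitors, 6 rose and 1 fell (median 0.75, camera adjusted p = 0.0221, adjusted p = 0.699 with an estimated correlation). Hes6, a promoter of neuronal differentiation, rose by 1.42 (SE 0.22, adjusted p = 0.00333), the transcription factor gene Sox11 by 2.0 (SE 0.38, adjusted p = 0.00648) and Gadd45g by 2.13 (SE 0.43, adjusted p = 0.00783). Of 15 tested markers of horizontal basal cells, the reserve stem cells, 2 rose and 1 fell, 1 and 0 adjusted over the list alone (median 1.24, camera adjusted p = 0.202). Trp63, the p63 gene that keeps these cells quiescent, rose by 1.82 (SE 0.41, adjusted p = 0.0116). Of 20 tested immature olfactory neuron markers, 1 rose and 5 fell, 3 and 5 adjusted over the list alone (median -0.53, camera adjusted p = 0.160). The adhesion gene Ncam1 fell, at -1.31 (SE 0.22, adjusted p = 0.00438) and the Ebf factor genes Ebf3 and Ebf1 at -2.97 (SE 0.56, adjusted p = 0.00618) and -2.72 (SE 0.55, adjusted p = 0.00803). Of 12 tested mature olfactory neuron markers, 2 rose and 1 fell, 2 and 3 adjusted over the list alone (median -0.50, camera adjusted p = 0.730). Gng13, a G protein subunit of odour transduction, rose by 3.78 (SE 0.79, adjusted p = 0.00897), at 0.702 ± 0.348 CPM in shCBX8, and the axon adhesion gene Kirrel3 fell, at -2.30 (SE 0.49, adjusted p = 0.00954). Progenitor markers that rose numbered 3 without shCTR 1, 2 or 5 or shCBX8 1 or 6. Horizontal basal cell markers that rose numbered 6 without shCTR 6. Immature neuron markers that fell numbered 3 without shCTR 1 or 5 or shCBX8 1 or 6 and 8 without shCBX8 2. Mature neuron markers that fell numbered 3 without shCBX8 2 and 4 without shCTR 6. The progenitor list lost its call without shCTR 2 or shCBX8 1 or 6 (adjusted p = 0.0543 to 0.0968), with library size alone (adjusted p = 0.0572), with unstranded counts (adjusted p = 0.160), without shCTR 1 and 2 (adjusted p = 0.175) and with the covariate (median 0.52, adjusted p = 0.595). The horizontal basal cell list passed without shCTR 6 (adjusted p = 0.0206), without a low-count filter (median 1.25, adjusted p = 0.0118) and with the replicate number as a block (median 1.92, adjusted p = 0.0158). Immature neuron markers passed with the covariate (median -1.05, adjusted p = 0.0124) and without shCTR 1 and 2 (median -0.49, adjusted p = 0.0353). The call of Trp63 ended without shCBX8 6 (adjusted p = 0.0511). The calls of Sox11, Trp63 and Ebf1 ended with the covariate (adjusted p = 0.105 to 0.193). Log2 fold changes in that fit were 1.72 (SE 0.67) for Sox11, 1.30 (SE 0.63) for Trp63 and -2.89 (SE 1.07) for Ebf1, and 7.59 for Gng13, which passed. The fit without shCTR 1 and 2 ended the calls of Sox11 and Trp63 (adjusted p = 0.0557 to 0.0771).

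Sustentacular and respiratory markers had higher values, and the lists of Bowman gland and microvillar cells did not pass. Of 17 tested sustentacular cell markers, 3 rose and 0 fell, 0 and 0 adjusted over the list alone (median 1.5, camera adjusted p = 0.0221, adjusted p = 0.819 with an estimated correlation). The keratin genes Krt8 and Krt18, which simple epithelia share, rose by 3.00 (SE 0.97, adjusted p = 0.0413) and 3.20 (SE 1.02, adjusted p = 0.0387), to 3129.8 ± 1348 CPM and 4100.2 ± 1973 CPM. Of 11 tested respiratory ciliated and secretory cell markers, 4 rose and 0 fell, 5 and 0 adjusted over the list alone (median 1.40, camera adjusted p = 0.0172, adjusted p = 0.652 with an estimated correlation). The ciliary genes Ccdc153 and Dnah5, an axonemal dynein, rose by 2.61 (SE 0.59, adjusted p = 0.0113) and 2.15 (SE 0.51, adjusted p = 0.0139). Of 7 tested Bowman gland and duct markers, 0 rose and 0 fell (median 1.44, camera adjusted p = 0.156). The water channel gene Aqp5 had a log2 fold change of 2.88 (SE 1.05, adjusted p = 0.0613), which did not pass. Of 8 tested microvillar cell markers, 0 rose and 1 fell, 0 and 0 adjusted over the list alone (median 0.01, camera adjusted p = 0.822). Avil, which encodes the actin-binding protein advillin, fell, at -1.06 (SE 0.31, adjusted p = 0.0295). Sustentacular markers that rose numbered 0 without shCTR 1, 2 or 5 or shCBX8 1 or 6, 1 without shCBX7 1 and 5 without shCTR 6 or shCBX7 2 or 5. Respiratory markers that rose numbered 0 without shCBX8 6 and 7 without shCBX8 2. Bowman gland markers that rose numbered 3 without shCBX7 2. The sustentacular call ended without shCBX8 6 (adjusted p = 0.0802) and with library size alone (adjusted p = 0.0775), and the respiratory call without shCBX8 6 (adjusted p = 0.0968), with a mean of at least 1 CPM (adjusted p = 0.0649), with unstranded counts (adjusted p = 0.0555) and with the covariate (median 1.78, adjusted p = 0.0687). The Bowman gland list passed with the replicate number as a block (median 1.69, adjusted p = 0.00826). Calls ended for Krt8 and Krt18 without shCTR 1, 2 or 5, shCBX7 1 or shCBX8 1 or 6 (adjusted p = 0.0526 to 0.111). Those of Ccdc153 and Dnah5 (1.33) ended without shCBX8 6 (adjusted p = 0.0565 to 0.0657). That of Avil ended without shCTR 6 or shCBX8 1 or 6 (adjusted p = 0.0572 to 0.122) and without a low-count filter (0.0743). The calls of Krt8, Krt18, Ccdc153 and Dnah5 ended with the covariate (adjusted p = 0.105 to 0.312). With it the log2 fold change was 2.53 (SE 1.61) for Krt8, 2.79 (SE 1.69) for Krt18, 2.30 (SE 1.01) for Ccdc153 and 2.57 (SE 0.95) for Dnah5, and -1.89 for Avil, which passed. Without shCTR 1 and 2 the calls of Krt8, Krt18, Ccdc153, Dnah5 and Avil ended (adjusted p = 0.0717 to 0.149).

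Cell cycle inhibitors fell in shCBX8. Of 7 tested cyclin-dependent kinase inhibitors, 0 rose and 6 fell (median -1.12, camera adjusted p = 0.0172, adjusted p = 0.642 with an estimated correlation). Beside Cdkn2a they included Cdkn1a, the p21 gene, at -0.76 (SE 0.20, adjusted p = 0.0184), Cdkn2d at -1.27 (SE 0.35, adjusted p = 0.0230) and Cdkn1b, the p27 gene, at -1.12 (SE 0.31, adjusted p = 0.0244). Of 36 tested mitosis genes, 0 rose and 0 fell (median -0.76, camera adjusted p = 0.0105, adjusted p = 0.819 with an estimated correlation). Mki67, the proliferation marker, had a log2 fold change of -1.58 (SE 0.56, adjusted p = 0.0543), which did not pass. Of 35 tested S phase genes, 5 rose and 0 fell, 0 and 0 adjusted over the list alone (median 0.11, camera adjusted p = 0.370). The replication genes Pcna and Fen1 rose by 0.52 (SE 0.13, adjusted p = 0.0195) and 1.01 (SE 0.27, adjusted p = 0.0215). Of 22 tested p53 target genes, 2 rose and 8 fell (median -0.24, camera adjusted p = 0.301). Pmaip1, the cell death gene Noxa, rose by 2.57 (SE 0.48, adjusted p = 0.00607), and Sesn1, Fas and Zmat3 fell, at -1.47 (SE 0.28, adjusted p = 0.00617), -2.0 (SE 0.41, adjusted p = 0.00825) and -0.83 (SE 0.17, adjusted p = 0.00911). Of 27 tested senescence-associated secreted factors, 8 rose and 3 fell, 8 and 5 adjusted over the list alone (median -0.34, camera adjusted p = 0.951). The protease inhibitor gene Serpine2 fell, at -2.20 (SE 0.27, adjusted p = 0.00156) and Igfbp7 at -2.80 (SE 0.49, adjusted p = 0.00476), while Plaur, the urokinase receptor gene, rose by 2.49 (SE 0.49, adjusted p = 0.00709).

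In the same lists, cyclin-dependent kinase inhibitors that fell numbered 0 without shCBX8 1 or 6 and 3 without shCTR 1. Mitosis genes that fell numbered 8 without shCTR 2 and 12 without shCBX8 2. S phase genes that rose numbered 0 without shCTR 1 or shCBX8 1 or 6, 2 without shCTR 2 or shCBX8 2 and 3 without shCBX7 2, and those that fell numbered 3 without shCBX8 2. Targets of p53 that fell numbered 3 without shCBX8 6 and 4 without shCBX8 1. Senescence-associated factors that rose numbered 3 without shCBX8 1, 4 without shCTR 1 and 5 without shCTR 5 or shCBX8 2 or 6, and those that fell numbered 5 without shCTR 6 and 12 without shCBX8 2. The call of the inhibitor list ended with the covariate (median -1.17, adjusted p = 0.0582), that of mitosis without shCBX8 6 (adjusted p = 0.155), and p53 targets passed without shCTR 2 (adjusted p = 0.0130) and without shCTR 1 and 2 (median -0.55, adjusted p = 0.00135). The S phase list passed without a low-count filter (median 0.14, adjusted p = 0.0376). Calls ended for Cdkn1a and Cdkn2d without shCBX8 1 or 6 (adjusted p = 0.0644 to 0.0934). Those of Cdkn1b and Fen1 ended without shCTR 1 or shCBX8 1 or 6 (adjusted p = 0.0528 to 0.0861). That of Pcna ended without shCTR 1 or 2 or shCBX8 1 or 6 (adjusted p = 0.0508 to 0.0796). The call of Cdkn1a also ended with library size alone (adjusted p = 0.0670) and that of Fen1 with unstranded counts (adjusted p = 0.205). The calls of Cdkn2d, Cdkn1b, Pcna, Fen1, Pmaip1, Sesn1, Fas, Zmat3, Igfbp7 and Plaur ended with the covariate (adjusted p = 0.0655 to 0.848). The log2 fold change with the covariate was -1.18 (SE 0.63) for Cdkn2d, -0.14 (SE 0.42) for Cdkn1b, 0.44 (SE 0.24) for Pcna, 0.64 (SE 0.46) for Fen1, 2.09 (SE 0.80) for Pmaip1, -0.67 (SE 0.37) for Sesn1, -0.74 (SE 0.59) for Fas, -0.92 (SE 0.28) for Zmat3, -2.18 (SE 0.79) for Igfbp7 and 1.39 (SE 0.71) for Plaur, and -1.17 for Cdkn1a, which passed. Omission of shCTR 1 and 2 ended the calls of Cdkn2d, Cdkn1b (-0.70), Pcna and Fen1 (adjusted p = 0.0757 to 0.151).

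Of the stress and signalling lists only interferon-stimulated genes passed camera in the main fit, although many single members changed. Of 22 tested genes of the integrated stress and unfolded protein responses, 6 rose and 3 fell, 7 and 4 adjusted over the list alone (median -0.02, camera adjusted p = 0.326). Chac1, a glutathione-degrading enzyme gene, rose by 2.45 (SE 0.28, adjusted p = 0.00146), the stress transcription factor genes Atf3 and Ddit3 by 3.31 (SE 0.55, adjusted p = 0.00406) and 0.83 (SE 0.14, adjusted p = 0.00419), and Asns, asparagine synthetase, by 0.95 (SE 0.16, adjusted p = 0.00427). Of 14 tested immediate early genes, 3 rose and 3 fell (median 0.02, camera adjusted p = 0.869). The phosphatase gene Dusp1 rose by 2.78 (SE 0.53, adjusted p = 0.00617) and Klf2 by 1.80 (SE 0.42, adjusted p = 0.0128). Of 17 tested ERK pathway targets, 1 rose and 2 fell, 1 and 0 adjusted over the list alone (median -0.02, camera adjusted p = 0.822). Ier3 rose by 1.94 (SE 0.19, adjusted p = 0.00124). Of 23 tested cholesterol biosynthesis genes, 0 rose and 5 fell, 0 and 3 adjusted over the list alone (median -0.49, camera adjusted p = 0.0865). Srebf2, the master regulator of sterol synthesis, fell, at -1.16 (SE 0.23, adjusted p = 0.00762). Of 29 tested interferon-stimulated genes, 0 rose and 0 fell (median -0.61, camera adjusted p = 0.0397, adjusted p = 0.819 with an estimated correlation). Ifit2 had a log2 fold change of -0.61 (SE 0.22, adjusted p = 0.0558), which did not pass. The median of the stress list was 0.15 and that of ERK targets 0.11 with library size alone, the opposite sign. Stress genes that fell numbered 1 without shCTR 5 or shCBX8 1 or 6. Immediate early genes that fell numbered 0 without shCBX8 1 or 6 and 1 without shCTR 2, 5 or 6. Cholesterol genes that fell numbered 1 without shCBX8 1 or 6, 3 without shCTR 5 or 6 and 11 without shCBX8 2. Interferon-stimulated genes that fell numbered 22 without shCBX8 2. The interferon call ended without shCTR 2 or 5, shCBX7 2 or shCBX8 1 or 6 (adjusted p = 0.0603 to 0.301), with a mean of at least 1 CPM (adjusted p = 0.0564) and with unstranded counts (adjusted p = 0.115), and cholesterol biosynthesis passed without shCTR 1 or 2 or shCBX8 2 (adjusted p = 0.00581 to 0.0400). Cholesterol biosynthesis passed as well after forward-strand counts were subtracted (median -0.55, adjusted p = 0.0406), with the covariate (median -1.26, adjusted p = 6.89e-11) and without shCTR 1 and 2 (median -0.78, adjusted p = 0.000209). ERK targets passed with the covariate (median -1.16, adjusted p = 0.00343) and stress genes without a low-count filter (median 0.01, adjusted p = 0.0487). The calls of Atf3, Ddit3, Asns, Dusp1 and Klf2 ended with the covariate (adjusted p = 0.0767 to 0.472). Log2 fold changes in that fit were 2.68 (SE 0.90) for Atf3, 0.40 (SE 0.16) for Ddit3, 0.53 (SE 0.22) for Asns, 2.83 (SE 0.93) for Dusp1 and 0.66 (SE 0.59) for Klf2, and -1.95 for Srebf2, which passed. The fit without shCTR 1 and 2 ended the calls of Dusp1 and Klf2 (adjusted p = 0.0526 to 0.0786).

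Of 22 tested TGF-beta and BMP targets, 5 rose and 7 fell, 5 and 8 adjusted over the list alone (median -0.62, camera adjusted p = 0.322). Tgfbi, a matrix protein induced by TGF-beta, fell from 196 ± 82.3 CPM to 3.23 ± 2.40 CPM, at -5.92 (SE 0.92, adjusted p = 0.00339), and the inhibitor of differentiation gene Id3 at -2.83 (SE 0.61, adjusted p = 0.00987). Of 17 tested Wnt pathway targets, 4 rose and 3 fell, 4 and 4 adjusted over the list alone (median -1.12, camera adjusted p = 0.301). The Wnt inhibitor gene Wif1 fell, at -3.99 (SE 0.70, adjusted p = 0.00480), and Rnf43, a ubiquitin ligase that removes Wnt receptors, rose by 2.61 (SE 0.56, adjusted p = 0.00984). Of 14 tested Notch pathway genes, 0 rose and 0 fell (median 0.33, camera adjusted p = 0.365). The Notch target gene Hes1 had a log2 fold change of 1.68 (SE 0.68, adjusted p = 0.0860), which did not pass. TGF-beta and BMP targets that rose numbered 1 without shCBX8 1 or 6, 2 without shCTR 1 or 5 and 3 without shCTR 2, and those that fell numbered 2 without shCBX8 1 and 4 without shCBX8 6. Wnt targets that rose numbered 1 without shCBX8 1 and 2 without shCTR 2 or 5 or shCBX8 6, and those that fell numbered 1 without shCTR 1, 5 or 6 or shCBX8 1 or 6 and 8 without shCBX8 2. The calls of Id3 and Rnf43 ended with the covariate (adjusted p = 0.0854 to 0.155). Its log2 fold changes were -2.84 (SE 1.24) for Id3 and 2.83 (SE 0.97) for Rnf43. Without shCTR 1 and 2 the calls of Id3 and Rnf43 ended (adjusted p = 0.0518 to 0.0640). The median, the mean and the camera direction differed in sign for 6 uncalled lists in shCBX8. These were senescence-associated factors (median -0.34, mean 0.05, down), microvillar markers (median 0.01, mean -0.05, down), endothelial markers (median -0.26, mean -0.02, up) and stress genes (median -0.02, mean 0.30, up). The others were ERK targets (median -0.02, mean -0.11, up) and immediate early genes (median 0.02, mean -0.08, up).

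The third comparison asked where the effects of the hairpins against Cbx8 and Cbx7 differ, which tests the difference itself (n = 3 and 3). Relative to shCBX7, Acta1 was higher in shCBX8 by 6.12 (SE 1.04, adjusted p = 0.00557), Mybpc2 by 5.96 (SE 1.34, adjusted p = 0.0130) and Xirp2, an actin-binding protein gene of striated muscle, by 5.98 (SE 0.76, adjusted p = 0.00260). Lrp2 was higher by 6.05 (SE 0.87, adjusted p = 0.00333) and Edn2 by 5.53 (SE 1.47, adjusted p = 0.0229). Inmt was lower at -8.83 (SE 1.76, adjusted p = 0.00894), as were Tgfbi at -6.13 (SE 0.95, adjusted p = 0.00411), Frem1, a basement membrane gene, at -5.43 (SE 1.1, adjusted p = 0.00957), Eln at -6.52 (SE 2.11, adjusted p = 0.0450) and Aspn at -5.64 (SE 1.66, adjusted p = 0.0332). In all, 4762 of 16669 genes differed, 2550 higher and 2212 lower in shCBX8 (53.5% higher), 2922 by more than 2-fold, and in 4683 the 2 groups of libraries did not overlap. Scaling by library size alone gave 4631 genes, 67.1% higher, with the median of all genes at 0.15. The count was 1848 without shCBX8 1, 1784 without shCBX8 6, 2730 without shCBX7 1 and 2900 without shCBX7 2. Calls ended for Edn2 without shCBX8 1 or 6 (adjusted p = 0.0624 to 0.0767) and with the covariate (4.98, SE 1.59, adjusted p = 0.0555), its value being 12.44 without shCBX7 5, for Eln without shCTR 1, shCBX7 1 or 2 or shCBX8 1, 2 or 6 (adjusted p = 0.0531 to 0.193; -3.14 without shCBX7 2) and for Aspn without shCBX7 1 or 2 or shCBX8 1 or 6 (adjusted p = 0.0579 to 0.116). With only the 2 groups compared, the calls of Edn2 and Aspn ended (adjusted p = 0.0533 to 0.0565), and that of Eln ended after forward-strand counts were subtracted (adjusted p = 0.0527).

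In this comparison 12 of the 31 lists passed camera, 5 upward and 7 downward in shCBX8, and none with an estimated correlation (adjusted p = 0.534 to 0.811 for the 12). The lists that were higher in shCBX8 held Hox genes and epithelial, progenitor and immune markers. Of 8 tested Hox genes, 4 were higher and 0 lower, 5 and 0 adjusted over the list alone (median 3.03, camera adjusted p = 0.000431). Of 17 tested sustentacular markers, 0 were higher and 0 lower (median 1.76, camera adjusted p = 0.00366). Of 11 tested respiratory markers, 5 were higher and 0 lower, 8 and 0 adjusted over the list alone (median 1.78, camera adjusted p = 0.00184). Of 14 tested progenitor markers, 5 were higher and 0 lower (median 0.75, camera adjusted p = 0.0418). Of 16 tested immune cell markers, 6 were higher and 0 lower (median 0.99, camera adjusted p = 0.0118). Hox genes that were higher numbered 2 without shCBX7 1 or shCBX8 1 or 6. Sustentacular markers that were higher numbered 4 without shCTR 2 and 14 without shCBX7 5. Respiratory markers that were higher numbered 3 without shCBX7 1 or shCBX8 1 or 6 and 8 without shCBX7 5. Progenitor markers that were higher numbered 2 without shCBX7 1 or shCBX8 1 or 6. Immune cell markers that were higher numbered 3 without shCBX8 6. The progenitor call ended without shCTR 6, shCBX7 2 or shCBX8 1, 2 or 6 (adjusted p = 0.0515 to 0.255), with library size alone (adjusted p = 0.0776) and with unstranded counts (adjusted p = 0.0886), and the immune call without shCBX7 2 (adjusted p = 0.0515) and with a mean of at least 1 CPM (median 0.02, adjusted p = 0.304).

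The lists called lower by camera in shCBX8 than in shCBX7 held fibroblast, matrix, developmental, cell cycle, sterol and interferon genes. Of 22 tested fibroblast markers, 0 were higher and 5 lower (median -2.04, camera adjusted p = 4.31e-05). Of 34 tested matrix genes, 3 were higher and 15 lower, 5 and 17 adjusted over the list alone (median -1.27, camera adjusted p = 0.000135). Of 65 tested developmental transcription factors, 12 were higher and 19 lower, 13 and 22 adjusted over the list alone (median -0.72, camera adjusted p = 0.0271). Of 7 tested cyclin-dependent kinase inhibitors, 0 were higher and 4 lower (median -1.08, camera adjusted p = 0.00997). Of 36 tested mitosis genes, 0 were higher and 1 lower, 0 and 0 adjusted over the list alone (median -1.13, camera adjusted p = 2.82e-05). Of 23 tested cholesterol biosynthesis genes, 0 were higher and 5 lower (median -0.55, camera adjusted p = 0.00366). Of 29 tested interferon-stimulated genes, 0 were higher and 0 lower (median -0.63, camera adjusted p = 0.0271).

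In this group, single omissions ended the calls of developmental transcription factors without shCBX7 2 or 5 or shCBX8 1 (adjusted p = 0.0600 to 0.0721) and interferon-stimulated genes without shCBX7 2 or 5 or shCBX8 1 or 6 (adjusted p = 0.0583 to 0.169). The background covariate ended both calls as well (adjusted p = 0.0513 and 0.0898), with that of cholesterol biosynthesis (adjusted p = 0.0690). That of developmental transcription factors also ended without a low-count filter (adjusted p = 0.0568) and with unstranded counts (adjusted p = 0.0899), and that of interferon-stimulated genes with a mean of at least 1 CPM (adjusted p = 0.0514) and with the replicate number as a block (adjusted p = 0.0667). Fibroblast markers that were lower numbered 0 without shCBX8 1 or 6, 2 without shCBX7 1 or 2 and 14 without shCBX8 2. Matrix genes that were higher numbered 0 without shCBX7 1 or 2 or shCBX8 1 or 6 and 1 without shCTR 1 or 5, and those that were lower numbered 5 without shCBX8 1 or 6, 6 without shCBX7 2 and 9 without shCBX7 1. Developmental transcription factors that were higher numbered 1 without shCBX7 1 or shCBX8 6, 4 without shCBX8 1 and 6 without shCBX7 2, and those that were lower numbered 7 without shCBX8 1 or 6, 10 without shCBX7 1 and 30 without shCBX8 2. Cyclin-dependent kinase inhibitors that were lower numbered 2 without shCBX8 1 or 6. Mitosis genes that were lower numbered 11 without shCTR 2 and 18 without shCBX8 2. Cholesterol genes that were lower numbered 1 without shCBX7 1 or shCBX8 1 or 6, 3 without shCBX7 2 and 14 without shCBX8 2. Interferon-stimulated genes that were lower numbered 21 without shCBX8 2. The other 19 lists did not pass camera in the main fit, with medians from -0.80 for Wnt pathway targets to 1.86 for Bowman gland and duct markers. Single omissions made some of them pass, namely horizontal basal cell markers without shCBX7 5 (adjusted p = 0.0163), immature neuron markers without shCTR 2 (adjusted p = 0.0482), Bowman gland markers without shCTR 2, shCBX7 5 or shCBX8 2 (adjusted p = 0.0161 to 0.0470) and p53 targets without shCTR 2 or shCBX7 2 (adjusted p = 0.0239 to 0.0437). Other settings did so too. With the covariate these were horizontal basal cell markers (adjusted p = 0.0186). After forward-strand counts were subtracted these were immature neuron markers (adjusted p = 0.0499). Without shCTR 1 and 2 these were p53 targets (adjusted p = 0.0398). Without a low-count filter these were PRC1 subunits, immature neuron markers, Bowman gland markers, p53 targets and TGF-beta and BMP targets (adjusted p = 0.00685 to 0.0416). With a mean of at least 1 CPM these were immature neuron markers (adjusted p = 0.0274). With the replicate number as a block these were horizontal basal cell markers, immature neuron markers and Bowman gland markers (adjusted p = 0.00218 to 0.0300). With only the 2 groups compared these were horizontal basal cell markers, Bowman gland markers and p53 targets (adjusted p = 0.0455 to 0.0496). The median, the mean and the camera direction differed in sign for 5 of these lists, namely senescence-associated factors, ensheathing and Schwann cell markers, smooth muscle markers, stress genes and immediate early genes.

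Both comparisons against control used the same 4 shCTR libraries. No gene passed in both with the same direction (edgeR, 0 of 16669), since none passed in shCBX7, while DESeq2 gave 49. At an unadjusted p under 0.05 there were 975 genes in shCBX7 and 7585 in shCBX8. Across genes, which are not independent replicates, the 2 sets of log2 fold changes had r = 0.15 and a covariance of 0.116. In 20 simulations of unchanged groups against these controls the median r was 0.44, the median covariance 0.0999 and the highest overlap 1. With the controls split 2 and 2 in 6 ways, r ran from -0.16 to 0.13, the covariance from -0.127 to 0.102, and the overlap reached 17 genes.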

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

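No test in this part was chosen after its result had been seen. For each named gene and measure the 4 shCTR libraries were checked for a single library far from the others by Dixon's test, and 19 of 244 had one, where chance gives about 5%, or 12.2. Of these, 10 were in shCTR 2, 6 in shCTR 6, 3 in shCTR 1 and 0 in shCTR 5. In shCTR 2 the high values were Cbx6 at 283 CPM (others 144 to 167), Ebf1 at 77.2 CPM (others 28 to 33.3), Eln at 31.6 CPM (others 0.498 to 3.56), Fmod at 48.5 CPM (others 0.518 to 3.29), Igfbp7 at 319.6 CPM (others 86.2 to 95.4), Lox at 694 CPM (others 134 to 229), Lpl at 158 CPM (others 2.94 to 4.87), Myh11 at 5.56 CPM (others 1.53 to 2.14) and Scube1 at 58.9 CPM (others 11.9 to 17.7), and the low value was Jarid2 at 15.1 CPM (others 18.3 to 18.4). In shCTR 6 the high values were Ccn2 at 196 CPM (others 48.6 to 67.9), Col17a1 at 19.7 CPM (others 1.70 to 2.81), Dbn1 at 124 CPM (others 97.2 to 101), Il1a at 1.47 CPM (others 0.20 to 0.396) and Krt13 at 37.9 CPM (others 0.651 to 2.89), and the low value was Xirp2 at 0.403 CPM (others 1.03 to 1.15). In shCTR 1 the high values were Mtf2 at 46.4 CPM (others 43.2 to 43.5), Ngfr at 7.21 CPM (others 5.01 to 5.13) and Sostdc1 at 14.5 CPM (others 0.921 to 2.38).

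The effects of the 2 hairpins differed in 4762 genes by a test of the difference itself. With 3 libraries in each group there are 10 splits, too few for a share under 5%, and the highest of the other splits gave 0 genes against 4762 for the real one, which was 1 of the 10. For shCBX8 against control, 1 of 35 splits, the real one, gave as many as 5478 genes. The highest other, shCTR 1, 2 and 5 against the rest, gave 342, so chance is unlikely for independent libraries. Whether shCBX8 1 and 6, the most alike libraries within a group (r = 0.990), are independent was not tested. For shCBX7 against control, the real count was 0, which all 35 splits must reach, so the splits decide nothing about chance. The highest of the other splits, with shCTR 1, shCTR 2 and shCBX7 2 on one side, gave 1194 genes, and the next highest gave 33. What these libraries share was not tested.

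Gm42418, a gene model that overlaps ribosomal RNA sequence, had 30462 CPM on the forward strand, which the comparisons do not use, in shCBX8 2, above the highest control value of 24472 CPM in shCTR 6.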

How the results depend on the processing

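Subtraction of forward-strand counts, the background covariate and omission of shCTR 1 and 2 were chosen after seeing the data, and the other alternatives were planned. Results named here changed with a setting, and the cause was not tested unless stated. The Cbx7 comparison gave 91 genes by DESeq2, 49 of them shared with the Cbx8 comparison, and the shared count was 17 in 1 of 6 splits of the controls. These splits, with 2 controls for each hairpin, gave 1795 to 5179 genes for Cbx8, and for Cbx7 35 in 1 and 0 in the other 5. The Cbx7 lists numbered 9 without a filter or without shCTR 1 and 2, and 0 by fry. The Cbx8 lists numbered 6 with unstranded counts. With an estimated correlation 0 lists passed in each comparison. A threshold of 0.01 left 1844 genes for Cbx8 and 1350 between the knockdowns. The Cbx8 count was 2311 with the background covariate and 2409 without shCTR 1 and 2, both fits with fewer libraries or degrees of freedom. The covariate turned the Cbx7 level from -0.67 to 1.78 and Actg2 in shCBX8 to 0.38. With each library left out, the counts ran from 0 to 41 genes for Cbx7, 2261 to 6193 for Cbx8, 1784 to 6005 between the knockdowns and 0 to 32 shared. Lists ran from 3 to 12, 4 to 12 and 9 to 15, and the target levels from -1.17 to -0.29 for Cbx7 and -1.40 to -1.20 for Cbx8. Under the other settings run, the counts of genes and lists stayed within 1.5 times, although fry called partly other lists than camera. Of 2448 pairs of a called gene and a setting in the Cbx8 comparison, 2105 kept the call, 342 lost it and 1 changed direction, and uncalled genes gained one in 84 pairs and changed sign in 6. The replicate number as a block gave 0, 6036 and 4661 genes and 7, 12 and 14 lists, -0.90 for Cbx7, -1.38 for Cbx8 and 0 shared genes. Whether the numbers pair the libraries stays open: 6 of 8 same-numbered pairs had correlated deviations over 0.1 (-0.08 to 0.67, median 0.22, against -0.06 for other pairs), and 6 of 10 libraries correlated best with their own number. Depth limits genes under 1 CPM, such as Hox genes.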

Other observations

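The test of forward-strand shares and the test of fibroblast markers between the knockdowns were chosen after their results had been seen, and the gene lists in this first paragraph were written after some of their members had been noticed, with only the remaining members tested. Hypotheses of a joint rise of lysosomal and of striated muscle contractile genes in shCBX8 were not borne out. Of 59 lysosomal genes, 12 rose and 6 fell in shCBX8, with a median log2 fold change of 0.10, and limma's camera did not pass. Of 24 contractile genes other than those noticed before, 2 rose and 1 fell, with a median of 0.20, and camera did not pass. In shCBX7 against control the median was 0.21 for lysosomal genes and -0.71 for contractile genes, and camera passed for both at an unadjusted 0.05, also with an estimated correlation, although edgeR called 0 members of either list. Relative to shCBX7, 8 of the 24 contractile genes were higher in shCBX8 and 0 lower (median 0.99), where camera passed with the preset correlation only. These lists were not part of the 31, and their values are given as hypotheses found in the same libraries.

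At an unadjusted p under 0.05, genes lower in shCBX7 outnumbered genes higher, 806 against 169 (82.7% lower). Neither background DNA in the control libraries nor their smaller depth is excluded as the cause. Lower genes made up 76.1% (340 against 107) after forward-strand counts were subtracted, and 79.2% after all libraries were thinned to 22763014 counts. A share over 70% had been set beforehand to argue against each, which was wrong, because only 447 and 706 genes were left where chance gives 779, so the excess itself was gone. That condition was added after these values had been seen. Background DNA may account for part of these genes, but the forward-strand shares cannot decide it. In the control libraries the lower genes had a median of 28.3% of their counts on the forward strand, against 0.283% for the higher ones. Median levels were 0.416 CPM for the lower and 49.0 CPM for the higher genes, and equally low genes that were not lower were not compared. The 91 genes called by DESeq2 were also at low levels, with medians of 0.583 CPM and 36.9% forward counts. An effect of the Cbx7 hairpin stays open.

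In shCBX8, fibroblast and matrix genes were lower and several epithelial lists higher. Background DNA in the controls is argued against for the fibroblast list, whose median was also -2.04 (quartiles -3.15 to -1.25) against shCBX7, where background was as low. A smaller share of fibroblasts in the shCBX8 cultures may account for part of the changes, as no cell sorting is named in the labels, none of the 22 markers is in another list, and abundant markers had lower means, with Postn at 2193 ± 2005 CPM in shCTR and 42.1 ± 13.8 CPM in shCBX8 and Vim at 2825 ± 265 CPM and 1497 ± 761 CPM. Both tests leave it open. Of 5468 called genes 69.0% changed as their slope on the fibroblast score in the other 7 libraries gives, against 58.2% of uncalled genes. With that score as a covariate 69 genes (1.26%) kept their call, as fibroblast loss alone would give. Over all calls the median log2 fold change size went from 1.13 to 0.64 and the median SE from 0.25 to 0.34. Of them 97.5% kept their sign. Since the score differs between groups, fewer fibroblasts and a direct hairpin effect cannot be told apart.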
